A study of Rattus norvegicus with 6 samples.

How the data were processed

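MicroRNA levels were measured in the terminal hindgut of fetal rats on 6 one-colour (Cy3) Agilent rat miRNA arrays. Per the labels' protocols, pregnant Sprague Dawley rats received ethylenethiourea (ETU, a thyroid peroxidase inhibitor that disturbs caudal development in rat embryos) by gavage at 125 mg/kg on gestational day 10, and control dams received distilled water. Fetuses taken on embryonic day 20 were sorted under a microscope by the presence of an anorectal malformation (ARM), and 1 cm of terminal hindgut was removed for RNA. Groups and replicate numbers were taken from the sample titles: 3 ARM samples and 3 control samples from healthy fetuses. The labels do not give the dam or litter of each fetus, or whether 1 sample is 1 animal, so p-values measure only the spread between these samples. Exposure to ETU and the malformation itself are joined in the ARM group.

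Per the file headers, the deposited intensity values were made with Agilent Feature Extraction 10.7.1.1, which subtracted a background from each spot and removed spatial trends, and no scaling between arrays had been applied. The value table deposited with the series held the same processed intensity for every spot, with a largest difference of 0 from the scanner files, so it is linear, not centred and not scaled between arrays, and the planned fit on it was the fit without scaling. The medians of its columns were 2.10, 2.61 and 2.84 for ARM replicates 1 to 3 and 2.44, 3.16 and 1.84 for control replicates 1 to 3. The second intensity used, the total gene signal per miRNA, was also computed by the authors' scanner software, per the file headers.

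Each array held 12843 features, of which 12128 were miRNA spots, covering 758 miRNAs with 1806 probes. Most miRNAs (594) had 2 probes, 132 had 4, 29 had 3 and 3 had 1. Control spots and spots that the software flagged as outliers were left out, and the remaining spots of a probe were averaged. A probe counted as detected on an array when at least 0.5 of its spots were well above background. Because most probes were not detected, each array was scaled to its 75th percentile over the 300 probes detected on all 6 arrays. The scaled signal was floored at 1 and converted to log2, and the mean over the probes of a miRNA was its level, including probes not above background on an array. Of the tested probes' values 2.97% lay below the floor, and values at the floor have no order. A miRNA was tested when a probe of it was detected on at least 3 of the 6 arrays, whatever the group, which left 230. A total of 485 miRNAs were detected on no array and 43 on 1 or 2. Names are those of the array design.

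ARM was compared with control by limma (lmFit and eBayes, version 3.58.1, in R 4.3.3) with Benjamini-Hochberg adjustment and a threshold of 0.05. All adjusted p-values of single miRNAs are from this test, and fold changes are ARM minus control on the log2 scale. Where a miRNA was not well above background on any array of a group, a fold is given only as a bound, the bright group's mean over the dim group's mean of the higher of the probe's own value and the array's lowest detected probe. In tests on simulated data with the levels and spread of these 230 miRNAs, 40 of them changed in each of 100 runs, 74.6% of 2-fold changes and 97.6% of 4-fold changes were recovered, and 4.71% of calls were false. These simulated miRNAs varied independently, which the measured ones do not.

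A total of 25 lists of miRNAs were fixed before the data were examined, as were the tests between the groups, the rule for naming miRNAs and all alternatives but the one that kept outlier-flagged spots. Lists with at least 3 tested members (17 of them) were tested with camera at a preset correlation of 0.01, then with an estimated correlation, and with fry, each adjusted over the 17 lists. The mean level of each list per array was compared by a two-sided exact permutation test, whose smallest p for 3 against 3 is 0.1. The 10 cell type lists (intestinal epithelium, stratified epithelium, smooth muscle, striated muscle, neurons and glia, endothelium, erythroid cells, leukocytes, mesenchyme, liver) also served as markers of other tissues in the piece. The other 15 were the Dlk1-Dio3 cluster, miR-17-92 and paralogues, let-7, miR-99/100 and miR-125, Hox-embedded miRNAs, miR-34, hypoxia, miR-29, inflammation and injury, miR-15/16, the miR-183 cluster, miR-30, miR-23/24/27, miR-181, and the miRNAs hosted by Igf2 and H19.

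The rule named up to 12 largest rises and 12 largest falls that passed the test with no overlap between the groups. Of the 5 rises and 26 falls that did so, 5 and 12 were named. It also named up to 4 members of each list with the highest mean level, and the 5 miRNAs with the highest level, 84 in all. Of lists that did not pass and had no called member, only the member with the highest level is named here, unless another was among the 5 highest of all. miR-322-3p, miR-542-5p, miR-133a-3p and miR-3584-5p were named after their values were seen.

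The 6 arrays lay on 2 slides, with ARM replicate 3 alone on slide 2. Alternatives covered the scaling between arrays, the background, the value per miRNA, the detection filter, the floor, the test, slide and replicate number as blocks, and each array left out. Keeping outlier-flagged spots was added after seeing the data, and the tests of the closing section were chosen as stated there. Neighbouring miRNA genes were taken from the RefSeq annotation of the rat assembly GRCr8, in which 208 of the 230 tested miRNAs were matched to a single gene; the array files name no genome build, so no coordinates are given.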

Results

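The data were miRNA levels in the terminal hindgut of 3 samples from fetal rats with ETU-induced anorectal malformation (ARM) and 3 from healthy fetuses (control), at embryonic day 20. Detected miRNAs numbered 211, 209 and 246 on ARM arrays 1 to 3 and 235, 241 and 207 on control arrays 1 to 3. The group means were 222 ± 20.8 and 228 ± 18.1 (SD, n = 3 each), a difference within that spread (two-sided exact permutation test, p = 1). Before scaling, ARM arrays were dimmer: the 75th percentile of the probes detected on all arrays was 203, 210 and 221 in ARM replicates 1 to 3 and 290, 278 and 225 in control replicates 1 to 3 (two-sided exact permutation test, p = 0.1, the smallest possible). Between 22.3% and 26.3% of miRNA spots were well above background, and no spot was saturated. Across the 230 tested miRNAs, which are not independent replicates, arrays correlated at 0.947 to 0.970 within ARM, 0.941 to 0.972 within control and 0.791 to 0.960 between groups. Control replicate 3 correlated better with ARM replicate 1 (0.960) than with control replicates 1 (0.941) and 2 (0.948). The number of arrays limits the precision of every value below.

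The comparison asked which miRNAs differ between malformed and healthy terminal hindgut. miRNAs of striated muscle and liver fell in ARM: miR-206-3p, a skeletal muscle miRNA, fell by 4.11 on the log2 scale (SE 0.87, adjusted p = 0.0385), and miR-122-5p, the dominant miRNA of hepatocytes, fell by 4.44 (SE 0.77, adjusted p = 0.0330), a size that rests on values near the floor, since it was well above background on 1 of 3 ARM arrays. Of the erythroid list, miR-451-5p and miR-486 fell, and so did 10 miRNAs of the imprinted Dlk1-Dio3 cluster. The rises were smaller, with miR-10b-5p, which lies among the Hox genes, up by 1.30 (SE 0.30, adjusted p = 0.0385). In all, 31 of 230 miRNAs passed the limma test, 5 higher and 26 lower in ARM, and 94 had an unadjusted p below 0.05. The 3 ARM arrays lay on one side of the 3 controls for all 31, and for 112 of the 230 tested miRNAs (48.7%, against 10% by chance). A looser criterion, 2-fold or more apart at an unadjusted p below 0.05, was met by 33 miRNAs, 9 higher and 24 lower. That count was 21 without ARM replicate 2, 18 without control replicate 1, 55 without control replicate 3 and 6 with normexp background correction.

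The number of calls depended on single arrays. It was 10 without ARM replicate 1, 92 without control replicate 3, and 0 without ARM replicate 2, ARM replicate 3, control replicate 1 or control replicate 2, where limma gave 56, 71, 64 and 74 miRNAs with an unadjusted p below 0.05. With slide as a block, which rests on the 2 ARM and 3 control arrays of slide 1, no miRNA passed (lowest adjusted p 0.0607, 78 with an unadjusted p below 0.05), while all 31 kept their sign. Within slide 1, miR-206-3p differed by -4.50 (SE 0.96), miR-122-5p by -4.33 (SE 0.91) and miR-10b-5p by 0.99 (SE 0.24); slide 2 held 1 array. The median fold change of all tested miRNAs was 0.17 and moved with the scaling, to 0.14 with the percentile over all probes, 0.21 with quantile normalization and -0.13 without scaling. The calls numbered 16 with normexp background correction, 14 with the scanner software's total gene signal, 87 with array weights and 0 without a detection filter (limma, 134 with an unadjusted p below 0.05). They were split into 10 higher and 28 lower with quantile normalization, and 1 higher and 30 lower without scaling.

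Striated muscle miRNAs were the list with the largest fall among those with several members. Of 5 tested, 4 fell and 1 did not pass, and all 5 were lower when adjusted over the list alone. The level of miR-206-3p was 5.77 ± 1.57 in ARM and 9.89 ± 1.23 in control (log2, SD, n = 3 each), that of miR-133b-3p 6.45 ± 0.51 and 9.62 ± 1.12, and that of miR-1-3p, shared by cardiac and skeletal muscle, 3.65 ± 1.09 and 7.27 ± 1.08. The related miR-1b fell as well (-1.64, SE 0.31), and miR-133a-3p, well above background on 1 of 3 ARM arrays, differed by -1.61 (SE 0.50, adjusted p = 0.0631). On every ARM array only 1 of the 2 probes of miR-1-3p and of miR-1b was detected, as was 1 of the 2 probes of miR-206-3p on ARM replicate 2, so these ARM levels include probes not above background. For miR-1b the same held on control replicate 3. The list median was -3.16 (camera, adjusted p = 0.00123; adjusted p = 0.635 with an estimated correlation), and -3.41 within slide 1. The list mean was 8.17, 7.91 and 6.32 in control replicates 1 to 3 and 4.96, 3.85 and 5.10 in ARM replicates 1 to 3 (two-sided exact permutation test, p = 0.1, the smallest possible). The median was -1.45 with normexp background correction, as was miR-1-3p, with miR-1b at -0.59, and -0.40 without a detection filter. With the total gene signal the median was 1.71 and not past the threshold. There miR-1-3p (1.71), miR-1b (2.17) and miR-133a-3p (2.05) changed sign, and miR-1b passed as higher in ARM (limma, adjusted p = 0.0462). miR-206-3p and miR-133b-3p kept their sign and their call there. Over all settings they ranged from -4.80 to -2.94 and from -3.79 to -2.41.

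miRNAs of the liver and erythroid lists also fell in ARM. miR-122-5p was detected on 1 of 3 ARM arrays and on all 3 controls, at 2.66 ± 1.69 and 7.10 ± 0.55 (log2, SD, n = 3 each). The 2 tested members of the erythroid list, miR-451-5p and miR-486, both fell (-1.64, SE 0.30, and -1.78, SE 0.28). Both were also lower when adjusted over the list alone. Which cells their RNA came from is not shown by the arrays. Of the 2 probes of miR-486, only 1 was detected on ARM replicates 1 and 2. With normexp background correction miR-122-5p was at -1.38, miR-451-5p at -1.01 and miR-486 at -0.59, all past the threshold; with the total gene signal miR-122-5p was at -5.77 and not called.

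**Figure D1:**
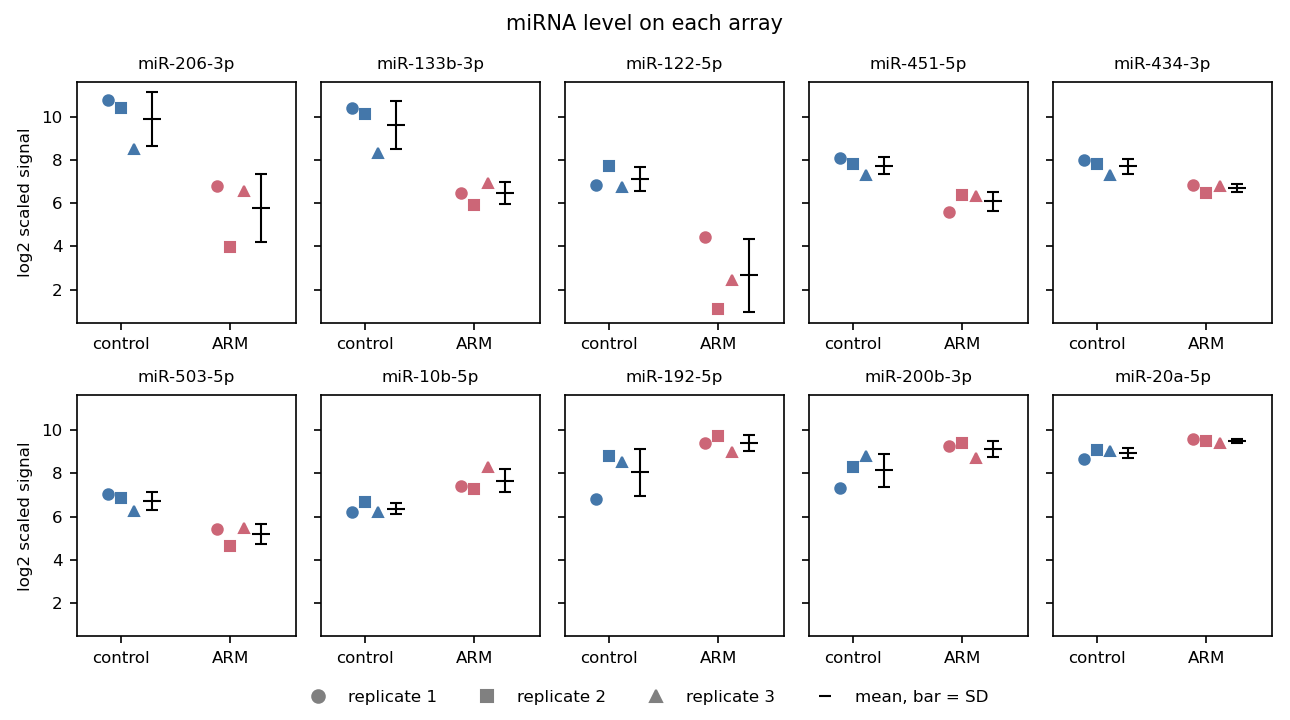
Level of 10 miRNAs on each array (y axis, log2 scaled signal; x axis, group; symbols mark replicate numbers, black marks the group mean with SD, n = 3). miR-206-3p lies at 5.77 in ARM and 9.89 in control on average, and control replicate 3 is the lowest control for both miR-206-3p and miR-133b-3p.

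The Dlk1-Dio3 cluster, a large group of miRNAs expressed from the maternal chromosome and abundant in fetal tissue, was lower in ARM. Of 34 tested members 10 fell, none rose and 24 did not pass, and 29 of 34 fold changes were negative; adjusted over the list alone, 22 were lower and 1 higher. The named falls were of miR-431 (-1.45, SE 0.35), miR-381-3p (-1.34, SE 0.31; detected on 2 of 3 ARM arrays), miR-495 (-1.27, SE 0.31), miR-410-3p (-1.01, SE 0.25) and miR-434-3p (-0.99, SE 0.23). Only 1 of 2 probes was detected for miR-495 on every ARM array and control replicate 3, and for miR-431 on ARM replicates 1 and 2. Among the members with the highest level, miR-127-3p differed by -1.04 (SE 0.28, adjusted p = 0.0511) and miR-494-3p by 0.28 (SE 0.23, adjusted p = 0.356), the latter negative without scaling. The list median was -0.79 (camera, adjusted p = 1.19e-08; adjusted p = 0.635 with an estimated correlation), and -0.87 within slide 1. The list mean was 5.51, 5.46 and 4.95 in control replicates 1 to 3 and 4.66, 4.44 and 4.82 in ARM replicates 1 to 3, so that control replicate 3 lay close to ARM. The striated muscle, erythroid and liver lists moved in the same direction, with differences of means of -2.83, -1.71 and -4.44. With normexp background correction the cluster median was -0.13 and miR-431 (-0.68), miR-381-3p (-0.31), miR-495 (-0.22) and miR-410-3p (-0.60) no longer passed; the median was -0.11 without a detection filter. With the total gene signal none of the 5 named falls passed and miR-495 was at 1.37; miR-431 (-1.76) and miR-495 (-1.58) also lost the call without scaling, and miR-410-3p (-0.84) with quantile normalization.

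miRNAs of the intestinal epithelium were higher in ARM as a list, although no single member passed the test. All 10 tested members had positive fold changes, with 9 higher when adjusted over the list alone. The hepatocyte nuclear factor targets miR-192-5p and miR-194-5p differed by 1.33 (SE 0.52, adjusted p = 0.104) and 1.31 (SE 0.48, adjusted p = 0.0925), and miR-200b-3p and miR-429, which maintain epithelial identity, by 0.99 (SE 0.39) and 0.90 (SE 0.36). The list median was 1.01 (camera, adjusted p = 0.00476; adjusted p = 0.635 with an estimated correlation), and 1.18 within slide 1. Control replicate 1 had the lowest list mean, 4.32 against 5.71 and 5.90 in the other controls and 6.14 to 6.78 in ARM, and without it the median was 0.61. It was 0.62 with normexp background correction and 0.86 with the total gene signal, where the list did not pass (camera with the preset correlation, adjusted p = 0.0534; 3.57e-05 to 0.0534 over the alternatives with that correlation). Other cell type lists moved beside it: the smooth muscle list by 0.56 and the stratified epithelium list by 0.51, in the same direction, and the striated muscle list in the opposite one.

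The miR-17-92 family of proliferation-linked miRNAs was also higher as a list. None of 10 tested members passed, all 10 fold changes were positive, and 7 were higher when adjusted over the list alone. miR-20a-5p differed by 0.56 (SE 0.19, adjusted p = 0.0706), miR-106b-5p by 0.53 (SE 0.17), miR-92a-3p by 0.48 (SE 0.18) and miR-19b-3p by 0.43 (SE 0.20). The list median was 0.53 (camera, adjusted p = 0.00334; adjusted p = 0.635 with an estimated correlation), 0.49 within slide 1, 0.22 without scaling and 0.25 without a detection filter. The striated muscle list moved in the opposite direction. Thus 4 of 17 lists passed with the preset correlation of 0.01 and none with the estimated one. The estimate was 0.83 for striated muscle, 0.58 for the Dlk1-Dio3 cluster, 0.93 for intestinal epithelium and 0.74 for miR-17-92. If members vary together to that degree, the p-values with the preset correlation are too small. The fry test called none for a shift in one direction (lowest adjusted p 0.0688) and 9 for changes in either direction. Among the 9 were striated muscle, the Dlk1-Dio3 cluster and miR-17-92 but not the intestinal epithelium.

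**Figure D2:**
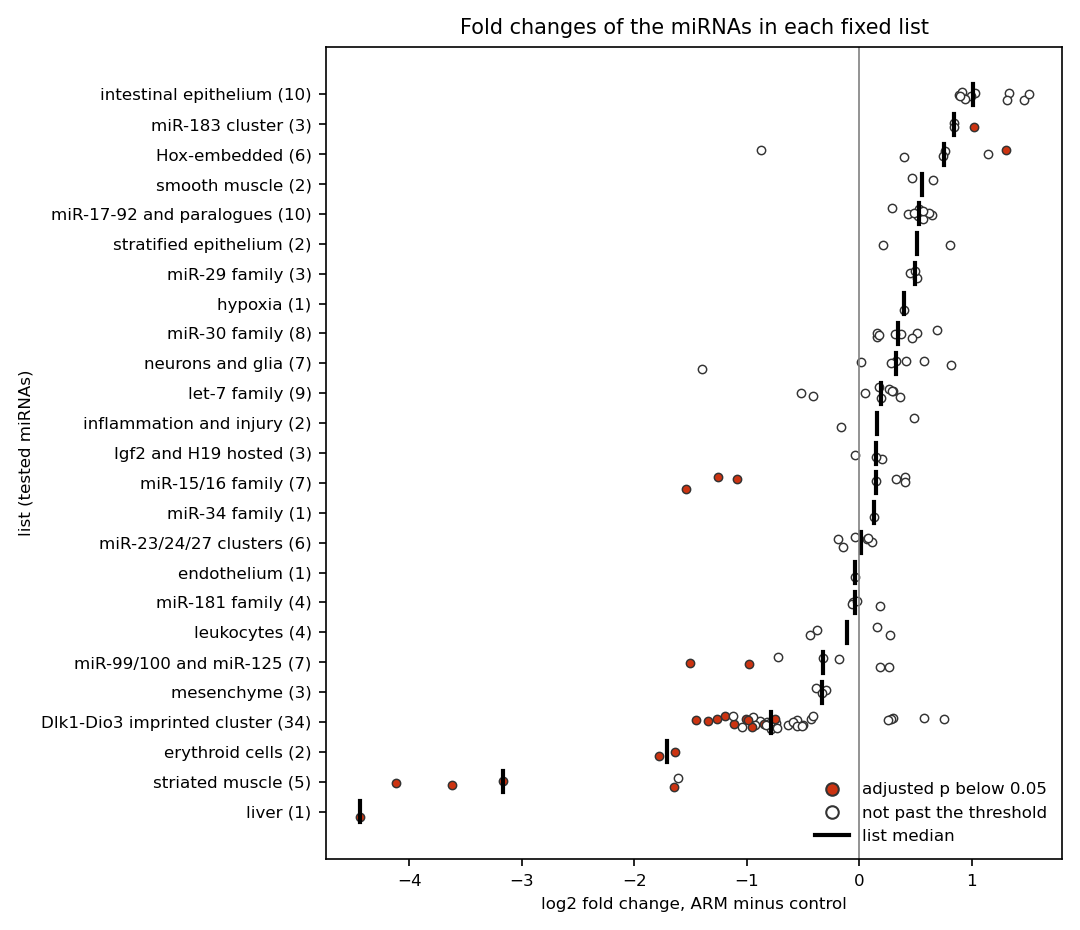
Log2 fold change, ARM minus control (x axis), of each tested miRNA in the 25 fixed lists (y axis, number of tested miRNAs in parentheses); filled points have an adjusted p below 0.05 and black bars are list medians. Striated muscle (-3.16) and the Dlk1-Dio3 cluster (-0.79) lie left of 0, and all 10 intestinal epithelium miRNAs lie right of it.

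Several further lists held single calls. In the miR-15/16 list, whose family restrains the cell cycle, miR-503-5p (-1.54, SE 0.30) and miR-322-5p (-1.09, SE 0.20) fell. So did miR-322-3p (-1.26, SE 0.31), the other arm of the miR-322 precursor. The remaining 4 members did not pass, among them miR-16-5p (0.15, SE 0.20, negative without scaling) and miR-15b-5p (0.41, SE 0.22). Only 1 of the 2 probes was detected for miR-322-3p on every array and for miR-503-5p on ARM replicates 1 and 2. With normexp background correction the 3 falls were at -0.68, -0.43 and -0.10, and miR-322-3p no longer passed. With the total gene signal miR-503-5p (-1.08) and miR-322-3p (-0.53) did not pass. The same 3 were lower when adjusted over the list alone. Its median (0.15, and -0.17 without scaling) was positive while its mean (-0.37) and the direction of camera (adjusted p = 0.498) were negative. In the miR-99/100 and miR-125 list, miR-99a-5p (-0.98, SE 0.24) and miR-99b-3p (-1.50, SE 0.34; detected on 2 of 3 ARM arrays) fell and 5 members did not pass, with miR-125b-5p at -0.32 (SE 0.22), miR-125a-5p at 0.19 (SE 0.20) and miR-99b-5p at 0.26 (SE 0.21), the last 2 negative without scaling. Adjusted over the list alone 2 were lower, and the list median was -0.32 (camera, adjusted p = 0.185). With the total gene signal miR-99a-5p was not called, and miR-99b-3p passed as higher in ARM, at 3.44 (limma, adjusted p = 0.0462). miR-99b-3p was at -0.07 with normexp background correction, -0.67 with the brightest probe and -0.80 with a floor of 10, and not called in these. Of 6 Hox-embedded miRNAs miR-10b-5p rose (not called without scaling, at 0.99, or with the total gene signal, at 1.14), miR-10a-5p differed by 0.76 (SE 0.26, adjusted p = 0.0792), miR-196b-5p by 0.40 (SE 0.18) and miR-196a-5p by -0.88 (SE 0.32, adjusted p = 0.0906), and the median was 0.75 (camera, adjusted p = 0.185); adjusted over the list alone 3 were higher and 1 lower. In the miR-183 cluster, expressed in sensory and epithelial cells, miR-182 rose by 1.02 (SE 0.23) at levels of 2.75 and 1.73, close to the floor, and was not called with a floor of 10 (0.35), normexp background correction (0.37) or the total gene signal (0.27). The other members, miR-183-5p (0.85, SE 0.26) and miR-96-5p (0.84, SE 0.23), did not pass, both turned negative with the total gene signal, all 3 were higher when adjusted over the list alone, and the cluster median was 0.85 (camera, adjusted p = 0.0694). The cluster passed with the percentile over all probes (0.81, adjusted p = 0.0418), without scaling (0.53, adjusted p = 0.00966), without a detection filter (0.84, adjusted p = 0.0427), and without control replicate 1 (0.64, adjusted p = 0.0389) or 2 (1.00, adjusted p = 0.0432). Its adjusted p ranged from 0.00966 to 0.912 over the alternatives with the preset correlation.

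The remaining 3 rises were of miRNAs that no list holds. miR-130b-3p rose by 0.74 (SE 0.19, adjusted p = 0.0396), and was not called without scaling (0.43) or with the total gene signal (0.60). miR-221-3p and miR-326-3p passed the test (adjusted p = 0.0385 and 0.0337) but were not well above background on any control array; miR-221-3p was at least 1.18-fold higher in ARM, and miR-326-3p had no bound above 1, so no fold is given for it. Neither passed with normexp background correction or without scaling. With the total gene signal miR-326-3p did not pass, and miR-221-3p passed as lower in ARM, at -2.46 (limma, adjusted p = 0.00173).

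No member of the other lists passed the test over all miRNAs, and adjusted over the list alone only the neuronal and glial list had calls, 1 higher and 1 lower. The mesenchymal miR-199a-3p (-0.29, SE 0.19) and miR-214-3p (-0.33, SE 0.19) were among the 5 miRNAs with the highest level, and their list had a median of -0.33 (camera, adjusted p = 0.241). In the smooth muscle list miR-143-3p differed by 0.47 (SE 0.24), in stratified epithelium miR-205 by 0.21 (SE 0.19; negative without scaling), and in endothelium miR-126a-3p by -0.04 (SE 0.18), which turned positive with quantile normalization. Neuronal and glial miRNAs had a median of 0.32 (0.28 with the member not above background in control at its bound), with miR-212-3p at 0.01 (SE 0.22; negative without scaling or with the percentile over all probes). Leukocyte miRNAs had one of -0.11, with miR-223-3p at 0.27 (SE 0.22; negative without scaling). The let-7 list had a median of 0.19, with let-7a-5p at 0.19 (SE 0.20), both negative without scaling, and the miR-30 list one of 0.34 (0.24 with such a member at its bound), with miR-30c-5p at 0.32 (SE 0.20; list adjusted p = 0.0977). Medians were 0.49 for miR-29 (miR-29a-3p 0.45, SE 0.35), 0.02 for miR-23/24/27 (miR-24-3p -0.04, SE 0.19), -0.04 for miR-181 (miR-181a-5p -0.06, SE 0.22) and 0.15 for the miRNAs hosted by Igf2 and H19 (miR-483-5p 0.20, SE 0.45; both negative without scaling). The median of miR-23/24/27 was positive and its mean negative (-0.02), and for miR-181 the median was negative and the mean positive (0.01); both medians turned sign with quantile normalization, and that of miR-23/24/27 also in the other scalings. Of the single-member or 2-member lists, miR-34a-5p differed by 0.13 (SE 0.17; negative without scaling), the hypoxia-induced miR-210-3p by 0.40 (SE 0.24), and miR-21-5p of the inflammation list by 0.49 (SE 0.21), with a list median of 0.16. miR-3473, also among the 5 highest, differed by -0.95 (SE 0.92, adjusted p = 0.431).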

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

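Keeping outlier-flagged spots was chosen after seeing the data and gave 36 calls, 30 of them among the 31 of the report; the other alternatives were planned. The 31 calls became 16 with normexp background correction, 14 with the total gene signal, 87 with array weights, 77 at an adjusted p below 0.10, and 0 without a detection filter or with slide as a block (limma, 134 and 78 with an unadjusted p below 0.05). They ranged from 0 to 92 when each array was left out. The miRNAs 2-fold apart (33) became 6 with normexp background correction and ranged from 18 to 55 with an array left out. The 4 list calls became 2 with the total gene signal, 10 without a detection filter (of 23 lists with enough members there, 2 of the 10, smooth muscle and erythroid cells, not being tested otherwise) and 0 with an estimated correlation. The cause was not tested. The ratio of the total gene signal to the sum of a miRNA's probe signals was 0.534 (median) where all probes were detected and 1.19 (quartiles 0.534 and 2.86) elsewhere. For miR-1-3p it was 13.1 in ARM replicate 1, with 1 of 2 probes detected, and 0.530 in control replicate 1, with 2. For miR-99b-3p, with 1 of 4 probes detected, it was 5.53 and 7.82 in ARM replicates 2 and 3 but 0.190 in control replicate 3, so the number of detected probes alone does not set it. The lists mesenchyme, miR-99/100 and miR-125, miR-30 and miR-183 passed without a detection filter, and mesenchyme also with normexp background correction. The difference in detected miRNAs between groups moved by less than the spread. Leaving out arrays also leaves fewer samples.

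With the total gene signal, called miRNAs changed sign: miR-1-3p to 1.71, miR-1b to 2.17, miR-99b-3p to 3.44, miR-495 to 1.37 and miR-221-3p to -2.46, and with them the striated muscle list to 1.71. Of these, miR-1b, miR-99b-3p and miR-221-3p passed in the opposite direction (limma, adjusted p = 0.0462, 0.0462 and 0.00173). They count among the calls with the total gene signal. Of the uncalled miRNAs named in the report, miR-133a-3p (2.05), miR-96-5p (-1.96), miR-183-5p (-0.48), miR-29a-3p (-0.23), miR-212-3p (-0.13) and miR-483-5p (-0.42), and the lists miR-183 (-0.48), miR-29 (-0.23), miR-23/24/27 (-0.22) and Igf2 and H19 (-0.21), also changed sign there. Other changes of sign were among results without a call, and of single miRNAs only those named in the report are listed. Without scaling these were let-7a-5p and its list (-0.12), miR-16-5p and its list (-0.17), miR-483-5p and its list (-0.11), the miR-23/24/27 list (-0.29), miR-205 (-0.11), miR-212-3p (-0.30), miR-223-3p (-0.038), miR-494-3p (-0.036), miR-125a-5p (-0.13), miR-99b-5p (-0.050) and miR-34a-5p (-0.18). With quantile normalization they were miR-126a-3p (0.019), miR-181a-5p (0.033) and the lists miR-181 (0.062) and miR-23/24/27 (-0.015). With the percentile over all probes they were miR-212-3p (-0.022) and the miR-23/24/27 list (-0.018). With normexp background correction they were miR-181a-5p (0.0016) and the lists leukocytes (0.18) and miR-181 (0.11). With the brightest probe they were miR-212-3p (-0.016), miR-483-5p (-0.13) and the lists miR-181 (0.015) and Igf2 and H19 (-0.10). With array weights they were miR-212-3p (-0.087), miR-126a-3p (0.034), miR-24-3p (0.087), miR-181a-5p (0.070), miR-483-5p (-0.11) and the lists miR-23/24/27 (-0.0020), miR-181 (0.044) and Igf2 and H19 (-0.11). With slide as a block they were miR-212-3p (-0.17), miR-24-3p (0.00065) and the miR-23/24/27 list (-0.068). The miR-181 list was at 0.042 without a detection filter, and the leukocyte list at 0.16 for miRNAs detected on all arrays and 0.0076 with a floor of 10. With an array left out, miR-126a-3p ranged from -0.11 to 0.073, miR-181a-5p from -0.24 to 0.11, miR-212-3p from -0.17 to 0.16, miR-24-3p from -0.17 to 0.10, miR-483-5p from -0.21 to 0.66, and the lists Igf2 and H19 from -0.18 to 0.32, leukocytes from -0.18 to 0.25, miR-181 from -0.12 to 0.10 and miR-23/24/27 from -0.13 to 0.036. Over all 84 miRNAs of the naming rule, the 21 called ones changed sign in 5 of 409 comparisons and lost the call in 184, and the 63 uncalled ones changed sign in 80 of 1255, over 32 miRNAs, and gained a call in 47.

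With replicate number as a block, 0 miRNAs passed (limma, 73 with an unadjusted p below 0.05), and the same 4 lists did. Deviations from the group mean correlated across miRNAs at -0.07, -0.28 and -0.21 between same-numbered samples, and no sample correlated best with its own number. The best matches lay under other numbers: ARM replicate 1 with control replicate 2 (0.42), 2 with 3 (0.47) and 3 with 1 (0.46). Deviations within a group depend on each other, so these values cannot show whether any samples shared a litter or a processing step.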

Other observations

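The tests of slides, other tissues, striated muscle in or beside the bowel, dilution, the spread among controls, neighbouring genes and other splits of the arrays were set down after the results had been seen. Only that of the spread among ARM arrays was set before.

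miRNA genes that neighbour each other in the rat assembly GRCr8 had similar fold changes as a set, though not in every group. In the group around miR-99b they ran from -1.50 for miR-99b-3p to 0.26 for miR-99b-5p, the other arm of the same precursor. On the X chromosome all 7 tested miRNAs of the group around miR-322 and miR-503, from 5 precursors, were lower in ARM, from -1.54 to -0.37. Of these 4 fell, among them miR-542-5p (limma, adjusted p = 0.0396). miR-542-5p was not called with normexp background correction, at -0.16, or with the total gene signal, at -0.80. Only 1 of its 2 probes was detected on each ARM array and on control replicate 3. A second X-linked group, that of miR-532, had all 5 miRNAs, from 4 precursors, lower, with a median of -0.68 and 1 call. Over 23 neighbour groups with 68 miRNAs, leaving out the Dlk1-Dio3 cluster, the SD of fold changes within groups was 0.391, against a median of 1.05 in 10000 shuffles (permutation p = 0.0001, the smallest they can give). Without the striated muscle groups these were 0.320 and 0.689 (permutation p = 0.0001). The groups count each tested arm of a precursor, so some of their members are arms of 1 gene, which the shuffles did not hold together. Likeness of such arms, shared transcription and the shared tissue of neighbouring genes may each account for the smaller SD, and they were not separated.

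miR-3473 and miR-3584-5p differed widely between arrays of one group. miR-3473 spanned 3.00 on the log2 scale among ARM arrays and 2.99 among controls, and miR-3584-5p 2.71 and 2.81. The called striated muscle miRNAs miR-206-3p (2.83 and 2.28) and miR-1-3p (2.08 and 1.96) also had wide ranges in both groups.

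The splits of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05. The 31 calls stood against at most 0 in another split, and the 33 miRNAs 2-fold apart against at most 8; in both, 1 of 10 splits, the real one, gave as many. List calls were different: 3 of the 10 splits gave at least the 4 calls of the real one, and the split of ARM replicate 1 and control replicates 1 and 3 from the rest gave 7.

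The lower striated muscle miRNAs in ARM have several candidate explanations. A difference between slides as the whole cause is argued against, since among the 5 arrays of slide 1 the list mean still differed by -3.06 (SE 0.85). RNA of other tissues in the piece that was cut would also give such a fall, and the liver miRNA miR-122-5p goes with it. Both of its 2 probes were detected on all 3 controls, at levels of 6.82, 7.74 and 6.74. It differed by -4.44 (SE 0.77) in the same direction, past the threshold, and by -1.38 with normexp background correction, still past it. Because it was well above background on 1 of 3 ARM arrays, the size of its fall is not settled, but its presence in the control pieces is. Of the erythroid list, miR-451-5p (-1.64, SE 0.30) and miR-486 (-1.78, SE 0.28) also fell. Both passed with normexp background correction (-1.01 and -0.59), but no array shows which cells their RNA came from. The leukocyte and endothelium lists had no call, with medians of -0.11 and -0.04. Less striated muscle in or beside the malformed bowel, the biological explanation that the groups give, cannot be told apart from a difference in what was cut. The list mean of the lowest control lay 1.22 above that of the highest ARM array. No array records what was dissected, or whether the striated muscle RNA came from the bowel or from tissue beside it.

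The intestinal epithelium list passed as higher in ARM only with the preset correlation (camera, adjusted p = 0.635 with an estimated correlation), as was true of all 4 lists that passed. All 10 of its members had positive fold changes, and none passed. If the difference is real, it may reflect dilution of the epithelium by other tissue in control pieces, or a source of variation that samples within a group share. Dilution would move the smooth muscle list as much, and the difference between the lists moved by 0.57 (SE 0.47), within 2 standard errors, so dilution and a change in the epithelium cannot be told apart with 3 arrays per group. The difference between the epithelium and mesenchyme lists moved by 1.46 (SE 0.55), over 2 standard errors, which dilution would give only if the diluting tissue also holds mesenchyme. Without the muscle, liver and erythroid lists, the difference between 2 controls correlated across 222 miRNAs, which are not independent, with ARM minus the remaining control. The absolute r was 0.459, 0.481 and 0.761 for the 3 pairs (the order within a pair is arbitrary). A shared source would give such values, but what unrelated variation would give was not computed, and the pairs share arrays. The 222 miRNAs reach beyond the epithelium list, so these values do not decide the question for that list. Among ARM arrays the same comparison gave 0.221, 0.377 and 0.532, on both sides of the 0.3 set beforehand, and left this open.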
